A study of Homo sapiens with 3 samples.

How the data were processed

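RNA was measured by sequencing in LX-2, an established line of human hepatic stellate cells, the cell type that lays down scar matrix in the injured liver. There were 3 libraries, 1 in each of 3 groups. One culture received the vehicle DMSO, one received transforming growth factor beta 1 (TGF-b1), and one received TGF-b1 with 10 μM of a natural small molecule that the labels call DP. All were taken at 48 h. With 1 library per group there were no replicates, so no difference has a replicate check, no p-value was computed, and each comparison is between libraries.

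The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to mapped fragments), 1 column per library, per the file headers, given to 2 decimals. Per the submitters' processing notes the genome build was GRCh38.p13 and the tools included BWA, Bowtie, Cufflinks and Cuffdiff. The role, order and versions of these tools, the strand setting and any filter are not given in the sources used here. FPKM is relative to each library's own mapped fragments, so a shift in a few abundant transcripts moves the values of all others. The columns also did not sum to the same total. Sums were 443566 FPKM for DMSO, 546754 for TGF-b1 and 429399 for TGF-b1+DP.

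The table held 17596 lines below its header. The 20 lines that carried annotation text in place of a gene were left out, which left 17576 genes, each symbol listed once. By Entrez identifier, 17336 of them (98.6%) had a transcript in GENCODE release 29 (GRCh38), used for transcript length, GC content and gene positions. A RefSeq table of another patch of the assembly (GRCh38.p14) was used for names, neighbours and the gene spans in the depth estimate. It matched 17509 genes. Elsewhere the length of a gene was that of its longest transcript.

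Differences were computed as log2((FPKM+1)/(FPKM+1)), with a pseudocount of 1 FPKM, which understates differences of low genes. Genes with a mean of at least 1 FPKM over the 3 libraries were kept (11327 genes). A gene was counted as higher or lower at a log2 difference of at least 1, a 2-fold difference on this scale. Values were used as deposited, with no further scaling. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with bedtools 2.31.1 and minimap2 2.31 for partner genes.

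Before the data were examined, 38 gene lists, the comparisons, the thresholds, the rule for named genes and a first set of other settings were fixed. For each list with at least 3 measured genes (34 lists), the median difference was given with its percentile among 10000 random lists of the same size matched on mean log2 expression in 20 bins. That percentile describes these libraries and is not a test. For differences corrected for length and GC content, 2000 random lists were drawn. The rule named the 10 largest differences in each direction for TGF-b1 against DMSO and for TGF-b1+DP against TGF-b1, and 5 in each direction for TGF-b1+DP against DMSO. Named genes were above 0 in both libraries compared and reached 5 FPKM in the higher one. The rule also took the largest members of the lists and 23 key genes. Genes named outside it are said to be so, and some genes that it names are not reported here.

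Both differences that involve the TGF-b1 library contain its chance values with opposite sign. The 3 values of each gene were therefore shuffled among libraries 1000 times, and the shuffled values are printed beside the observed ones. A gene was taken to share reads where its exons overlapped those of another measured gene by at least 100 bp on either strand, or where at least 200 bases matched another measured gene's transcript at 97% identity or more. This held for 3884 genes, whose values are uncertain.

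The procedure was tested on simulated data. In simulated libraries of 11327 genes, 163 of 200 genes made 3-fold different (81.5%) and 188 of 200 made 4-fold different (94.0%) were recovered for TGF-b1 against DMSO, with 0 and 2 unchanged genes called. Of 100 lists of 25 genes with no shift, 5 lay outside the central 95% of random lists, and 100 of 100 lists shifted by 0.5 lay above it. The unshifted lists were drawn from the same simulated values as the random lists, so about that many outside follows from the construction. The simulated noise was smaller than the spread of the real differences (SD 0.615 for TGF-b1 against DMSO) and held no trend with length or GC content. These rates therefore check the computation and are not error rates for these libraries.

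Depth is not given in the sources used here. In short genes with little intron, FPKM times the RefSeq gene span in kilobases clustered at multiples of 0.0500 in DMSO, 0.0480 in TGF-b1 and 0.0485 in TGF-b1+DP. If that step is 1 fragment, the libraries held about 20.0, 20.8 and 20.6 M fragments. The clustering was partial: 63.4%, 63.3% and 61.1% of the values used lay within 0.2 of a whole step. A window that wide holds a large share of values even without clustering. Each step was also the best of a range tried on the same values. These depths are therefore rough estimates, and no count test was run. At 20.0 M fragments, 5 FPKM on a 1 kb transcript corresponds to 100 fragments.

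Those settings were other pseudocounts, filters, scalings and thresholds, means in place of medians, and restricted gene sets. Another 3 were chosen after seeing the data: differences corrected for transcript length and GC content, the same with mean expression added, and the removal of genes that share reads. A count was taken as stable within 1.5 times its main value. A list median was taken as stable when it moved by less than a normal 95% half-width of the random lists' medians. That rule was settled after the numbers under a stricter limit of 1 SD had been seen, and the closing section gives both.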

Results

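Gene expression was measured in LX-2 cells, a human hepatic stellate cell line, treated for 48 h with DMSO, with TGF-b1, or with TGF-b1 and 10 μM DP. Each group was 1 library, so the differences below have no replicate check and describe these libraries. Of 17576 genes, 16099 were above 0 in DMSO, 15796 in TGF-b1 and 15829 in TGF-b1+DP. The 100 most abundant genes held 24.4%, 30.5% and 26.0% of the summed FPKM.

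The comparison of TGF-b1 with DMSO asks what the cytokine did to these cells. Known targets of TGF-beta signalling were higher: 19 of 33 measured SMAD targets by at least 1 on the log2 scale and none lower by that amount, with a list median of 1.08 (percentile 100 of random lists). PMEPA1, a feedback inhibitor of the pathway, was at 0.37 FPKM in DMSO and 12.9 in TGF-b1 (log2 difference 3.34). TGFBI, a secreted matrix protein, was at 132 and 901 FPKM (2.76), and SNAI1, a transcription factor of mesenchymal cells, at 1.57 and 15.3 (2.67). LTBP3 (-0.96) and SKI (-0.72) were the lowest members.

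As deposited, contractile genes of myofibroblasts went both ways in TGF-b1. Of 29 measured, 4 were higher and 3 lower, with a median of 0.50 (percentile 94.4). It was 0.20 with the same total FPKM, and 0.56 (percentile 100) after correction for transcript length and GC content, chosen after seeing the data. After that correction 5 contractile genes were higher and none lower. The median of 5 epithelial markers was 0.72 (percentile 99.0), or 0.42 with the same total, 0.13 without genes that share reads and -0.04 with no filter on low values. Lower as deposited among the contractile genes were ACTN4 (-1.50, shares reads) and FLNA (-1.37), which crosslink actin. ACTA2, which encodes smooth muscle actin (gene ID 59, chromosome 10, 88935074 to 88991339, GRCh38), was at 21.1 FPKM in DMSO and 78.1 in TGF-b1 (1.84), and TAGLN at 53.9 and 220.1 (2.01). LOX, which crosslinks collagen, was at 13.1 and 71.8 FPKM (2.37), FN1, fibronectin, at 174 and 809 (2.21), and CCN2 at 26.1 and 144 (2.42). TIMP1, an inhibitor of matrix metalloproteinases, was at 271 and 1111 FPKM (2.03), and TGFB1 itself at 87.5 and 222 (1.33). ACTA2, LOX and TGFB1 have exons that overlap a neighbouring gene, and TAGLN also shares reads by the criteria above, so their values are less certain. GAPDH was at 4552 FPKM in DMSO, 5836 in TGF-b1 and 4147 with DP, and ACTB at 3042, 5050 and 3505.

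Collagens went both ways. COL1A2 was at 1.22 FPKM in DMSO and 5.91 in TGF-b1 (1.64), and COL1A1 (gene ID 1277, chromosome 17, 50183289 to 50201632) at 295 and 604 (1.03), or 0.73 with libraries scaled to the same total. COL3A1 was at 34.9 and 33.1 FPKM (-0.07, above 0 under median-of-ratios and upper-quartile scaling). COL12A1 (-1.85) and COL8A1 (-1.62) were lower. Of 18 measured collagens 3 were higher and 3 lower, with a median of -0.14 (percentile 32.7). It was 0.04 under median-of-ratios scaling and -0.43 with the same total FPKM. After correction for length and GC content the collagen median was 0.68 (percentile 100), with 7 higher and 2 lower. Among other matrix proteins 9 of 25 were higher and 3 lower, such as LAMA4 (-1.46), with a median of 0.43 (percentile 99.9). It was 0.14 with the same total FPKM, 0.13 above 5 FPKM, -0.01 with no filter and 0.69 after correction for length and GC content. For collagen processing genes the median was 0.12, or -0.09 with the same total FPKM and 0.42 (percentile 99.9) after correction for length and GC content, with PLOD2 at 1.31 and TGM2, which shares reads, at -0.66.

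The named genes with the largest positive differences also included FOXS1 (3.51), a forkhead transcription factor, MYCT1 (3.03), CGB8 (2.90) and LOC102723728 (3.79), which was listed at 0 with DP. Lower in TGF-b1 were ADCY6 (-2.98), an adenylyl cyclase, and SEMA3B (-2.61), a semaphorin, with KIAA0754 (-2.56). Of these 20 genes 11 have an overlapping or near-identical measured gene: CGB8, EIF3CL (5.57), CXCR5 (3.12), LOC102724200 (2.59), ABCF2-H2BE1 (-4.49), MYO18A (-3.25), NOMO2 (-2.95), EIF3C (-2.71), HSPG2 (-2.62), NOMO3 (-2.59) and PKD1 (-2.56). Their values are uncertain, and 3 of the 20 (LOC102723728, ABCF2-H2BE1 and KIAA0754) had no GENCODE transcript to search for near-identical copies.

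Lists of protein synthesis and respiration genes had positive medians for TGF-b1 against DMSO. The median of 78 cytoplasmic ribosomal protein genes was 0.86 (percentile 100), with 21 higher and none lower, as for RPL39 (1.30). Of these 78 genes 21 share reads with another gene. For 44 nuclear genes of oxidative phosphorylation it was 0.69 (percentile 100), with 2 higher, COX6C (1.08) and NDUFA4 (1.03), and none lower. These medians were 0.56 and 0.39 with the same total FPKM, and 0.53 and 0.32 after correction for length and GC content. As deposited, other genes of like abundance were also higher. The central 95% of matched random lists ran from 0.376 to 0.632 for the ribosomal list and from 0.059 to 0.475 for the respiratory list. In the same library the 1410 shortest genes had a median of 0.43 and the 1410 longest of -0.47. Of 50 cell cycle genes 6 were lower, as for MKI67 (-1.66), and 44 lay within 1, of which 10 were above 0. Their median was -0.34 (percentile 0.00), or -0.16 under median-of-ratios scaling and -0.63 with the same total. After correction for length and GC content 1 was lower and the median was -0.41, and the median of 10 histone genes, listed as a sign of RNA quality, was -0.55 (percentile 0.05), against -0.15 as deposited.

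In all, 262 genes were higher and 762 lower in TGF-b1 than in DMSO among 11327. That split was 584 and 486 under median-of-ratios scaling, and 103 and 1563 with the same total FPKM. The median over all genes moved by 0.16 and -0.26 under these. After correction for length and GC content the split was 267 and 204.

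**Figure D1:**
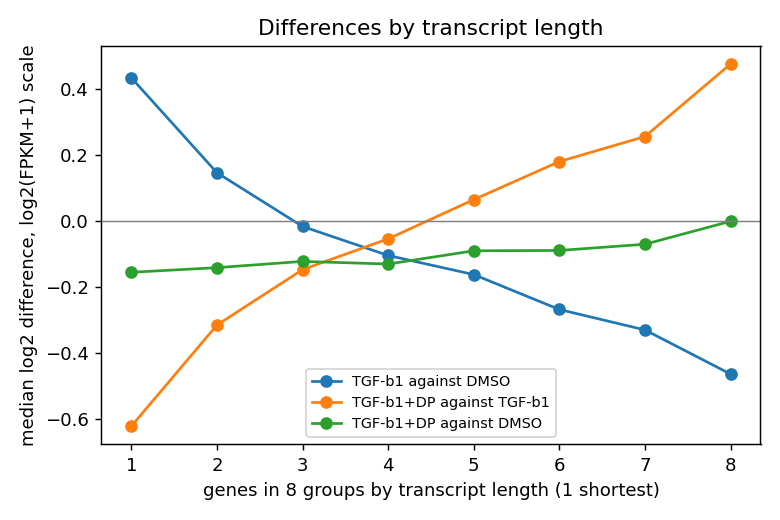
Median log2 difference, on the log2(FPKM+1) scale, of genes in 8 groups by transcript length for the 3 comparisons. For TGF-b1 against DMSO the median goes from 0.43 in the shortest genes to -0.47 in the longest, and for TGF-b1+DP against DMSO from -0.16 to -0.00126.

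The comparison of TGF-b1+DP with TGF-b1 asks what DP did in cells that also received TGF-b1. Of 29 contractile genes 5 were lower and 5 higher with DP, with a median of -0.01 (percentile 99.1), or 0.34 with the same total FPKM. The median of 5 epithelial markers was -1.0 (percentile 0.32), or -0.67 without genes that share reads, -1.85 above 5 FPKM and -0.19 with no filter. Higher as deposited among the contractile genes were ACTN4 (1.61) and FLNA (1.44). ACTA2 was at 78.1 FPKM with TGF-b1 and 6.79 with DP (log2 difference -3.34), TAGLN at 220.1 and 59.8 (-1.86), and LOX at 71.8 and 12.1 (-2.48). HES1, a transcription factor of the Notch pathway (gene ID 3280, chromosome 3, 194136145 to 194138732), was at 20.4 and 1.49 FPKM (-3.10). In DMSO HES1 was at 3.17 FPKM, so it was higher in TGF-b1 (2.36) and within 1 of DMSO with DP (-0.74). COL3A1 was at 33.1 and 10.8 FPKM (-1.53), COL1A1 at 604 and 349 (-0.79), and COL1A2 at 5.91 and 3.24 (-0.70). Of 18 collagens 4 were higher and 1 lower, with a median of 0.22 (percentile 95.6), or 0.52 with the same total FPKM. After correction for length and GC content the collagen median was -0.27 (percentile 2.25), with 1 higher and 3 lower.

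FN1 was at 809 FPKM with TGF-b1 and 1686 with DP (1.06, or 0.70 after correction for transcript length and GC content, chosen after seeing the data). TIMP1 was at 1111 and 1717 FPKM (0.63), and PMEPA1 at 12.9 and 16.3 (0.32). CCN2 was at 144 and 139 FPKM (-0.04, above 0 with the same total). Of the 19 SMAD targets that were higher in TGF-b1, 4 were lower with DP by at least 1, and 14 were still higher than in DMSO by at least 1. Among all 33 measured SMAD targets 3 were higher and 5 lower with DP, or 1 and 5 after correction for length and GC content. The lowest were SNAI1 (15.3 and 4.17 FPKM, -1.66) and TGFBI (901 and 382, -1.24), and the highest PODXL (1.79) and LTBP2 (1.34). The list median was 0.11 (percentile 87.8), or 0.38 with the same total FPKM and -0.01 after correction for length and GC content.

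**Figure D2:**
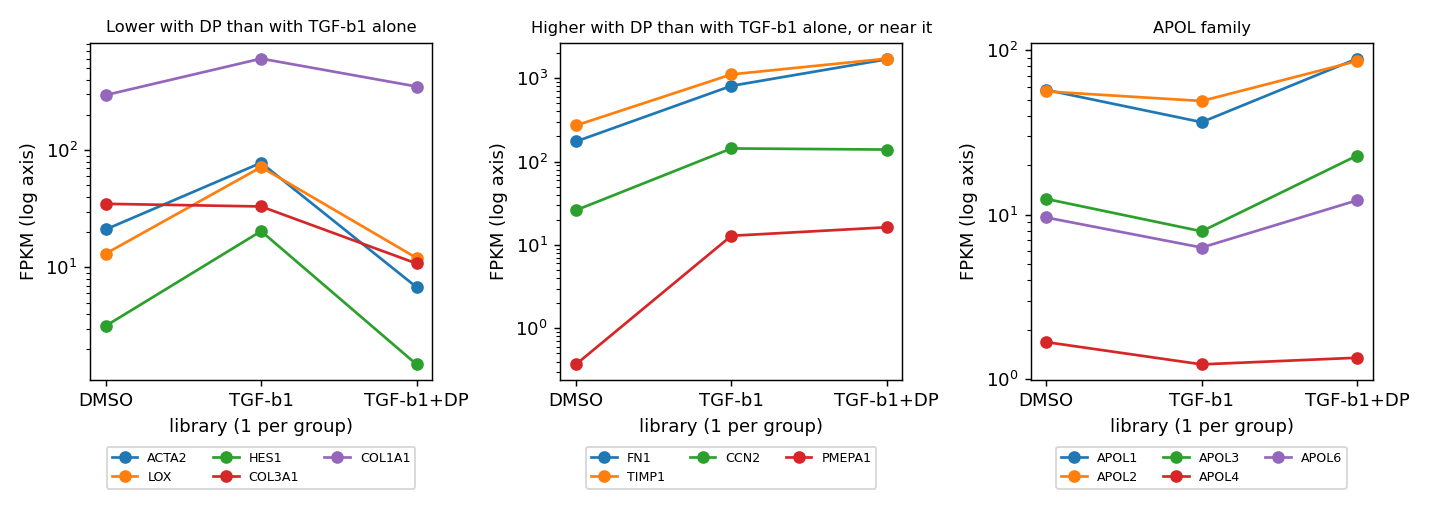
FPKM of key genes in the 3 libraries, 1 library per group, on log axes. ACTA2 goes from 78.1 FPKM with TGF-b1 to 6.79 with DP, while FN1 goes from 809 to 1686.

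Lists of inflammation, interferon response and matrix proteolysis genes had positive medians for DP against TGF-b1. Of 39 measured interferon-stimulated genes 24 were higher and none lower, with a median of 1.12 (percentile 100), led by OAS2 (2.61) and OAS1 (2.55). IFITM2 (-0.73, shares reads) and IFITM3 (-0.40) were the lowest. Of 27 cytokine and NF-kB genes 15 were higher, with a median of 1.07 (percentile 100), led by TRAF1 (3.37) and CCL5 (2.75), with CCL2 (-0.99) and CCL7 (-0.95) lowest. Of 22 matrix proteases and inhibitors 8 were higher and 1 lower, with a median of 0.75 (percentile 100). MMP1, interstitial collagenase, was at 9.43 and 228 FPKM (4.46) and MMP14 at 13.1 and 104 (2.90), while SERPINE2 was at 204 and 77.1 (-1.39).

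In the APOL family, named in the study's title through APOL2, 2 of 5 measured members were higher with DP than with TGF-b1 alone by at least 1, and none than in DMSO. APOL2 (gene ID 23780, chromosome 22, 36226203 to 36239954) was at 56.1 FPKM in DMSO, 49.1 in TGF-b1 and 85.8 with DP (0.79 for DP against TGF-b1). APOL1 was at 57.3, 36.5 and 88.8 FPKM (1.26) and APOL3 at 12.5, 7.92 and 22.9 (1.42). APOL6 was at 9.61, 6.31 and 12.2 FPKM (0.85) and APOL4 at 1.68, 1.23 and 1.35 (0.08), while APOL5 was listed at 0 in DMSO and with DP. The median of 5 measured members was 0.85 (percentile 99.5), or 1.16 with the same total FPKM. With the same total APOL2 was at 1.14, APOL1 at 1.6, APOL3 at 1.74 and APOL4 at 0.268. The number of members that reached 1 against TGF-b1 alone therefore depended on the scaling.

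Further genes higher with DP were SERPINA1 (1.93 and 88.5 FPKM, 4.93), a protease inhibitor, SERPINB2 (4.34), IGFBP5 (3.74), ESM1 (3.52), SLAMF8 (3.11), MYEOV (3.09) and HAS2 (3.01), which makes hyaluronan. Lower were MEST (106.7 and 6.60 FPKM, -3.83), CPA4 (-3.34), FOXS1 (-2.66), ID1 (-2.75), an inhibitor of helix-loop-helix factors, and, among genes that share reads, EIF3CL (-5.88), CXCR5 (-3.12), TIAF1 (-2.88) and LOC102724200 (-2.69). ABCF2-H2BE1 (4.86) was higher, SERPINB2 overlaps SERPINB10 and MEST overlaps COPG2. BMP targets had a median of -0.45 (percentile 0.56), or -0.24 with the same total FPKM, -0.14 with no filter and -0.74 at a pseudocount of 0.1, with ID3 at -1.76 and GREM1 at 1.57. Cholesterol genes had a median of -0.54 (percentile 1.18), or -0.23 with the same total and -0.28 after correction for length, GC content and abundance, with IDI1 at -1.28.

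Of 26 calcium store genes 4 were higher with DP and none lower. Among 36 genes of the PERK and ATF4 list 1 was higher and 3 lower, among 35 ER chaperones 1 and 1, and among 14 Notch genes 1 and 3. After correction for length and GC content these splits were 1 and 0, 1 and 3, 0 and 0, and 1 and 4, in the same order. ATP2A2, the calcium pump, was at 97.3, 54.0 and 115 FPKM in DMSO, TGF-b1 and TGF-b1+DP (1.08 for DP against TGF-b1, and 0.86 after correction for length and GC content). EIF2AK3, which encodes PERK, was at 4.69, 4.90 and 3.73 FPKM (-0.32). DDIT3, which shares reads with another gene, was at 27.5, 30.3 and 25.9 FPKM (-0.22). HSPA5 was at 148, 189 and 183 FPKM (-0.05), and both were above 0 with the same total. With the same total FPKM the medians of the following 4 lists were above 0, at 0.09, 0.11, 0.29 and 0.26. The PERK and ATF4 list had a median of -0.21 (percentile 36.7, or 2.10 after correction for length and GC content), with PPP1R15A at 1.75 and NUPR1 at -1.11. ER chaperones had -0.23 (percentile 33.1), with ATF6 (shares reads) at 1.11 and SEC61B at -1.01, and calcium store genes -0.02 (percentile 64.2), with ATP2B1 at 1.73 and SARAF at -0.86. Notch genes had -0.07 (percentile 22.8), or -0.28 (percentile 0.50) after that correction, with HES1 and HES4 (-1.27) lowest and DTX4 at 1.38.

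In all, 701 genes were higher and 483 lower with DP than with TGF-b1 alone, or 1439 and 121 with the same total FPKM and 376 and 280 after correction for length and GC content. Ribosomal protein genes had a median of -0.91 and respiratory chain genes of -0.85 (both percentile 0.00), or -0.56 and -0.52 with the same total and -0.42 for both after correction for length and GC content. Matched random lists as deposited ran from -0.754 to -0.451 and from -0.598 to -0.128 (central 95%). The signs of the 2 medians are the reverse of those for TGF-b1 against DMSO. Both comparisons contain the TGF-b1 library, so a deviation of that library alone would reverse them. For TGF-b1+DP against DMSO the 2 medians were -0.03 (percentile 94.6) and -0.18 (5.90), the first above 0 with the same total.

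Genes that differed between TGF-b1 and DMSO were counted by their difference between TGF-b1+DP and TGF-b1. Of 262 genes higher in TGF-b1 than in DMSO, 112 (42.7%) were lower with DP by at least 1, 137 lay within 1, and 13 were higher again. Of 762 lower genes, 327 (42.9%) were higher with DP. Independent lists would share 11.2 and 47.2 genes, and shuffling each gene's 3 values gave 26.8% (range 22.1 to 32.9) and 36.1% (28.9 to 41.9). With the same total FPKM the 2 counts were 29 of 103 and 838 of 1563, and under median-of-ratios scaling 207 of 584 and 250 of 486. After correction for length and GC content they were 103 of 267 (38.6%) and 97 of 204 (47.5%). The shuffled shares are for values as deposited only.

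Across genes, which are not independent replicates, the difference of TGF-b1 against DMSO correlated with that of TGF-b1+DP against TGF-b1 at r = -0.68 (Spearman rho -0.73), against -0.50 in shuffled data (-0.54 to -0.46). The covariance was -0.28, against -0.18 shuffled. The TGF-b1 library is part of both differences and cannot be split, so part of the excess may come from that library. Its own variance over genes was 0.28, against 0.10 for DMSO and 0.16 for TGF-b1+DP, and an r below -0.50 follows from that order whatever its source. TGF-b1 against DMSO and TGF-b1+DP against DMSO, which share the DMSO library, correlated at 0.32, below the 0.50 of shuffled data, with a covariance of 0.10 against 0.18.

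The comparison of TGF-b1+DP with DMSO takes differences, as deposited, without the TGF-b1 library. That library still entered the filter on mean FPKM and the expression matching of the random lists. Targets of TGF-beta signalling were higher, with 20 of 33 higher, 1 lower and a median of 1.16 (percentile 100). FN1 was at 174 FPKM in DMSO and 1686 with DP (3.27), TIMP1 at 271 and 1717 (2.66), and CCN2 at 26.1 and 139 (2.37). ACTA2 was lower, at 21.1 and 6.79 FPKM (-1.50), as was COL3A1 at 34.9 and 10.8 (-1.60). LOX (-0.11) and GAPDH (-0.13) lay near their DMSO levels, and were above 0 under median-of-ratios scaling.

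Lists of inflammatory and proteolytic genes had positive medians against DMSO too. The medians were 1.00 for cytokine and NF-kB genes (14 of 27 higher, 1 lower), 0.78 for interferon-stimulated genes (15 of 39 higher, 1 lower) and 1.04 for proteases and inhibitors (11 of 22 higher, 1 lower; 0.64 with no filter on low values), all at percentile 100. CCL5 was at 5.15 and 54.2 FPKM (3.17), IL1B at 15.5 and 111 (2.76), IFI44 at 3.88 and 28.1 (2.58) and MMP1 at 21.0 and 228 (3.38). The median of 4 macrophage and leukocyte markers, of 11 in the table, was 0.47 (percentile 99.0), or 0.15 as a mean, 0.83 at a pseudocount of 0.1 and 0.01 with no filter on low values. The named genes were MYCT1 (5.19), SERPINA9 (4.48), SLAMF8 (4.46), HAS2 (4.42) and INHBA (4.25), an activin subunit.

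Of 50 measured cell cycle genes 14 were lower with DP than in DMSO and none higher, with a median of -0.83 (percentile 0.00), as for KIF20A (108 and 28.7 FPKM, -1.88, shares reads) and E2F2 (-2.04). The median of the histone genes was -0.66 (percentile 0.01), and that of 5 epithelial markers -0.88 (percentile 0.06), or -0.24 and -0.28 with no filter. BMP targets had a median of -0.93 (percentile 0.00), with ID1 at 24.8 and 3.08 FPKM (-2.66) and ATOH8 at -2.59, while GREM1, a BMP antagonist, was at 129 and 519 (1.99). Stellate quiescence genes, 10 measured of 26 in the table, had -0.58 (percentile 0.16), or -0.23 with no filter and -0.96 at a pseudocount of 0.1, with PCDH7 at -1.75 and NGFR at -1.46. NRF2 targets had -0.44 (percentile 0.00), or -0.29 under median-of-ratios scaling, with NQO1 at -1.66 and PIR at -1.23. Among the largest negative differences were CPA4 (-4.14), MEST (-3.29), RARRES2 (-3.23) and SEMA3B (-2.88).

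Counts were 278 higher and 326 lower, or 358 and 212 under median-of-ratios scaling and 317 and 209 after correction for length and GC content. Of the 262 genes higher in TGF-b1 than in DMSO, 72 were also higher with DP than in DMSO, 187 lay within 1 of DMSO and 3 were lower. In shuffled data 36.0% stayed higher, against 27.5% observed, and independent lists would share 6.43 genes.

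**Figure D3:**
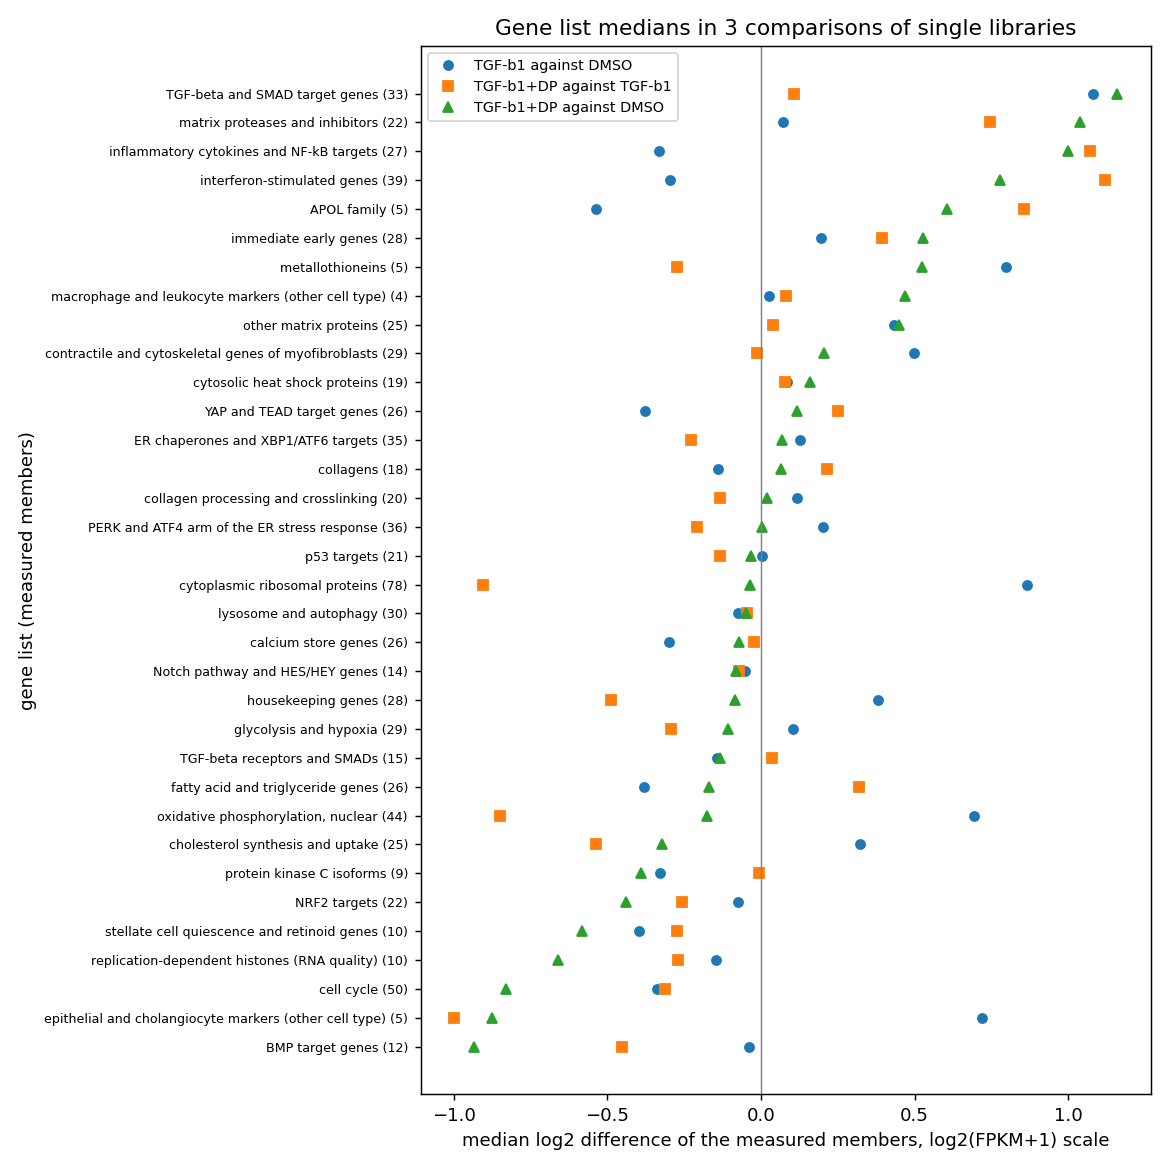
Median log2 difference of the measured members of each gene list, on the log2(FPKM+1) scale, in the 3 comparisons, with the number of measured members in brackets. Interferon-stimulated genes lie at 1.12 for TGF-b1+DP against TGF-b1 and cell cycle genes at -0.83 for TGF-b1+DP against DMSO.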

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

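All 3 corrections (length and GC, abundance added, genes that share reads removed) were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Values below are those that moved by over 1.5 times for counts, by over 0.1 for r, by over the 95% half-width of random lists for list medians, or that changed sign; the cause was not tested unless the setting itself sets the number of genes. The 95% limit was settled after the numbers under a stricter limit of 1 SD had been seen. Of 45 list medians (44 at 5 FPKM), those that moved by less than 1 SD and by less than the 95% limit were 34 and 39 at a pseudocount of 0.1, 40 and 44 at 0.5, 36 and 44 with means, 26 and 31 with no filter, 32 and 39 at 5 FPKM. They were 23 and 34 under median-of-ratios, 44 and 45 under upper-quartile, 25 and 30 under same-total scaling, and 20 and 36 with length and GC content removed, 19 and 35 with abundance as well, 36 and 41 without genes that share reads. These 45 are the list medians outside the central 95% of random lists, of 102 in all, so medians near 0 are not among them. For the 45, over the settings fixed beforehand, 302 values were stable, 48 moved and 9 changed sign. Of all 102 medians, 36 changed sign under at least 1 of the 3 scalings. The 1 FPKM filter was applied after scaling, so a list's measured members could differ. Key-gene differences of at least 1 kept their sign under every setting run for them, and COL1A1, ATP2A2 and FN1 each had a difference that no longer reached 1 in some of them. Smaller differences could also come to reach 1, as for APOL2 in TGF-b1+DP against TGF-b1 (0.795 as deposited, 1.14 with the same total FPKM). At the estimated depth, 1 FPKM on a 1 kb transcript is about 20 fragments, a counting SD of 22.4%, so low genes are the least certain.

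With means of the members, for TGF-b1 against DMSO the list mean was -0.0806 for YAP targets. The mean for TGF-b1+DP against TGF-b1 was -0.0888 for heat shock proteins. With a pseudocount of 0.1, 1211 genes were lower for TGF-b1 against DMSO, 533 genes were lower for TGF-b1+DP against DMSO and 576 genes lower in TGF-b1 went the other way with DP. At this pseudocount list medians for TGF-b1+DP against DMSO were 1.22 for proteases and inhibitors, 1.3 for SMAD targets, -1.2 for BMP target genes, -0.962 for quiescence genes, 1.2 for NF-kB and cytokine genes and 0.961 for interferon-stimulated genes. With a pseudocount of 0.5, for TGF-b1+DP against DMSO the list medians were 1.18 for NF-kB and cytokine genes. With no filter on low values, for TGF-b1 against DMSO the list medians were -0.012 for other matrix proteins and -0.0426 for epithelial markers. Unfiltered list medians for TGF-b1+DP against TGF-b1 were 0.0426 for contractile genes and -0.189 for epithelial markers. Unfiltered list medians for TGF-b1+DP against DMSO were 0.0 for other matrix proteins, 0.643 for proteases and inhibitors, 1.01 for SMAD targets, -0.649 for BMP target genes, -0.227 for quiescence genes, 0.306 for immediate early genes, -0.0426 for protein kinase C isoforms, 0.0 for metallothioneins, -0.241 for histones, 0.0143 for macrophage markers and -0.279 for epithelial markers. With a mean of at least 5 FPKM, 206 genes were lower for TGF-b1+DP against DMSO. Above 5 FPKM list medians for TGF-b1 against DMSO were 0.131 for other matrix proteins. Above 5 FPKM list medians for TGF-b1+DP against TGF-b1 were -1.85 for epithelial markers. Above 5 FPKM list medians for TGF-b1+DP against DMSO were -0.0307 for collagens, 1.54 for proteases and inhibitors, -0.031 for ER chaperones, 1.19 for NF-kB and cytokine genes and 0.0905 for protein kinase C isoforms. Under median-of-ratios scaling, 584 genes were higher for TGF-b1 against DMSO, 486 genes were lower for TGF-b1 against DMSO, 212 genes were lower for TGF-b1+DP against DMSO and 207 genes higher in TGF-b1 went the other way with DP. Median-of-ratios list medians for TGF-b1 against DMSO were 1.05 for ribosomal protein genes. Median-of-ratios list medians for TGF-b1+DP against DMSO were 0.609 for other matrix proteins, 0.358 for contractile genes, 1.31 for SMAD targets, 0.223 for ER chaperones, -0.669 for cell cycle, -0.161 for cholesterol genes, 1.21 for NF-kB and cytokine genes, 0.938 for interferon-stimulated genes, 0.683 for immediate early genes and 0.323 for heat shock proteins. With the members as deposited, the NF-kB and cytokine value was 1.16. Under scaling to the same total, 103 genes were higher for TGF-b1 against DMSO, 1563 genes were lower for TGF-b1 against DMSO, 1439 genes were higher for TGF-b1+DP against TGF-b1, 121 genes were lower for TGF-b1+DP against TGF-b1, 29 genes higher in TGF-b1 went the other way with DP and 838 genes lower in TGF-b1 went the other way with DP. Same-total list medians for TGF-b1 against DMSO were 0.138 for other matrix proteins, -0.627 for cell cycle, -0.659 for fatty acid genes, -0.0751 for immediate early genes, 0.564 for ribosomal protein genes and 0.391 for respiratory chain genes. Same-total list medians for TGF-b1+DP against TGF-b1 were 1.06 for proteases and inhibitors, 0.335 for contractile genes, -0.232 for cholesterol genes, 0.646 for fatty acid genes, 1.47 for NF-kB and cytokine genes, 1.45 for interferon-stimulated genes, 0.724 for immediate early genes, -0.557 for ribosomal protein genes and -0.52 for respiratory chain genes. The NF-kB and cytokine value with the members as deposited was 1.41. At a 1.5-fold threshold, 1392 genes were higher for TGF-b1 against DMSO, 2367 genes were lower for TGF-b1 against DMSO, 1913 genes were higher for TGF-b1+DP against TGF-b1, 1903 genes were lower for TGF-b1+DP against TGF-b1, 617 genes were higher for TGF-b1+DP against DMSO, 1153 genes were lower for TGF-b1+DP against DMSO, 934 genes higher in TGF-b1 went the other way with DP and 1305 genes lower in TGF-b1 went the other way with DP. At a 4-fold threshold, 38 genes were higher for TGF-b1 against DMSO, 29 genes were lower for TGF-b1 against DMSO, 83 genes were higher for TGF-b1+DP against TGF-b1, 30 genes were lower for TGF-b1+DP against TGF-b1, 70 genes were higher for TGF-b1+DP against DMSO, 28 genes were lower for TGF-b1+DP against DMSO, 16 genes higher in TGF-b1 went the other way with DP and 15 genes lower in TGF-b1 went the other way with DP. With the length and GC trend removed, 204 genes were lower for TGF-b1 against DMSO, 376 genes were higher for TGF-b1+DP against TGF-b1, 280 genes were lower for TGF-b1+DP against TGF-b1, 209 genes were lower for TGF-b1+DP against DMSO, 97 genes lower in TGF-b1 went the other way with DP and r was -0.55. Length-corrected list medians for TGF-b1 against DMSO were -0.0114 for YAP targets, -0.112 for fatty acid genes, 0.531 for ribosomal protein genes and 0.323 for respiratory chain genes. Length-corrected list medians for TGF-b1+DP against TGF-b1 were -0.423 for ribosomal protein genes and -0.42 for respiratory chain genes. Length-corrected list medians for TGF-b1+DP against DMSO were 0.243 for collagens, -0.723 for cell cycle and 1.17 for NF-kB and cytokine genes. With the abundance trend removed as well, 194 genes were lower for TGF-b1 against DMSO, 369 genes were higher for TGF-b1+DP against TGF-b1, 279 genes were lower for TGF-b1+DP against TGF-b1, 204 genes were lower for TGF-b1+DP against DMSO, 90 genes lower in TGF-b1 went the other way with DP and r was -0.544. Abundance-corrected list medians for TGF-b1 against DMSO were -0.0362 for YAP targets, 0.415 for ribosomal protein genes and 0.222 for respiratory chain genes. Abundance-corrected list medians for TGF-b1+DP against TGF-b1 were 1.35 for interferon-stimulated genes, -0.321 for ribosomal protein genes and -0.349 for respiratory chain genes. Abundance-corrected list medians for TGF-b1+DP against DMSO were 1.2 for proteases and inhibitors, 1.32 for SMAD targets, 1.17 for NF-kB and cytokine genes and 1.01 for interferon-stimulated genes. Without genes that share reads, 64 genes higher in TGF-b1 went the other way with DP. Unshared-gene list medians for TGF-b1+DP against TGF-b1 were 0.0113 for contractile genes. Unshared-gene list medians for TGF-b1+DP against DMSO were 1.32 for proteases and inhibitors, 0.386 for contractile genes, -0.853 for quiescence genes and 0.972 for interferon-stimulated genes.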

Other observations

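The tests on total FPKM, on shuffled libraries (corrected values included) and on the sum of EIF3C and EIF3CL were chosen only after the result was seen, and the corrections for length, GC content and abundance were added after seeing the data, with the predictions for them written before their results.

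Lists not described above stood as follows, as medians for TGF-b1 against DMSO, TGF-b1+DP against TGF-b1 and TGF-b1+DP against DMSO. Immediate early genes were at 0.19 (-0.08 with the same total FPKM), 0.39 (0.72 with the same total) and 0.53 (0.31 with no filter), with EGR2 at 2.47 in the first. Metallothioneins were at 0.80, -0.27 and 0.52 (the first 0.38 and the last 0.00 with no filter), led by MT1X at 2.22. Fatty acid genes were at -0.38, 0.32 and -0.17, with CPT1A at -1.23 in the first; with the same total the first 2 were -0.66 and 0.65, after correction for length and GC content -0.11 and 0.13, and under median-of-ratios scaling the last was -0.02. YAP and TEAD targets were at -0.38, 0.25 and 0.12, with TGFB2 at 2.51. The first was -0.08 as a mean, -0.65 with the same total and -0.01 after correction for length and GC content, the second 0.58 with the same total, and the last 0.24 under median-of-ratios scaling. Heat shock proteins were at 0.09, 0.08 and 0.16, with HSPE1 at 1.37. Glycolysis and hypoxia genes were at 0.10, -0.29 and -0.11, with VEGFA at 14.7, 43.3 and 43.1 FPKM. The TGF-beta receptor list was at -0.14, 0.04 and -0.13, with TGFBR2 at 1.04 in the second. Protein kinase C isoforms were at -0.33, -0.01 and -0.39 (the last 0.09 above 5 FPKM), with PRKCA at -0.94. Targets of p53 were at 0.00, -0.13 and -0.03, with XPC at 1.60 in the second. Lysosome genes were at -0.07, -0.05 and -0.05, and housekeeping genes at 0.38, -0.49 and -0.08, with POLR2A at -1.43. Contractile genes were at 0.20 in the last (0.36 under median-of-ratios scaling, 0.12 with no filter, 0.39 without genes that share reads). HSPE1 and XPC share reads with another gene. The sign of at least 1 of the 3 medians also differed under another scaling for metallothioneins, heat shock proteins, glycolysis and hypoxia genes, TGF-beta receptors, protein kinase C isoforms, p53 targets, lysosome genes and housekeeping genes, so no direction is given for them.

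Markers of other cells and of RNA quality were few. Epithelial markers (5 measured) were at 0.72 (percentile 99.0), -1.0 (0.32) and -0.88 (0.06) in the 3 comparisons, in the same order, with KRT18, which shares reads, at 388, 890.1 and 203 FPKM. With no filter on low values these medians were -0.04, -0.19 and -0.28, and above 5 FPKM the second was -1.85, so their size, and for TGF-b1 against DMSO their sign, depended on the filter. For TGF-b1+DP against TGF-b1, 3 of the 5 were lower, as for KRT8 (-1.85), which also shares reads. Macrophage markers were at 0.03, 0.08 and 0.47 (percentiles 78.4, 57.6 and 99.0) over 4 genes (the first -0.16 with the same total, the last 0.01 with no filter), with CD68 at 48.5, 21.3 and 54.8 FPKM. From the hepatocyte list SERPINA1 alone passed the filter, and from the endothelial list TIE1 alone (7.91, 4.66 and 18.4 FPKM). Histone genes were at -0.15 (percentile 61.7), -0.27 (3.58) and -0.66 (0.01), the last -0.24 with no filter. After correction for length and GC content the first 2 histone medians were -0.55 (0.05) and 0.34 (97.8). The lists of mitochondrially encoded and of nuclear noncoding RNAs had no measured gene.

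After correction for length and GC content, 20 of 102 list medians came to lie outside the central 95% of random lists and 6 no longer did. For TGF-b1 against DMSO, medians that came to lie outside included 0.43 for the PERK and ATF4 list (percentile 100), 0.32 for Notch genes (99.5), 0.32 for proteases and inhibitors (99.4) and 0.38 for glycolysis and hypoxia genes (99.95). On the negative side were NRF2 targets at -0.23 (0.40), cytokine and NF-kB genes at -0.29 (0.20) and interferon-stimulated genes at -0.29 (0.00). As deposited, the signs of the PERK and ATF4, Notch, protease, glycolysis and NRF2 medians differed between scalings. For TGF-b1+DP against TGF-b1, other matrix proteins went from 0.04 (81.6) to -0.37 (0.05). Medians that no longer lay outside were, for TGF-b1 against DMSO, those of YAP targets, fatty acid genes and metallothioneins, for TGF-b1+DP against TGF-b1 those of contractile and fatty acid genes, and for TGF-b1+DP against DMSO that of ER chaperones.

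The positive medians of ribosomal protein and respiratory chain genes for TGF-b1 against DMSO were weighed against technical explanations, as a hypothesis. The median over the 122 genes of both lists was 0.80, and most of these genes did not reach 1. A shift of all abundant genes would leave the ribosomal list among matched random lists, and it lay at percentile 100; with the same total FPKM the median was 0.497, so a difference in totals does not account for it alone. Correction for transcript length and GC content lowered the median to 0.428 (bootstrap SD 0.0479), with 0.531 for ribosomal and 0.323 for respiratory genes, and adding abundance lowered it to 0.339. The value of 0.428 passed the bound written beforehand against the length and GC explanation by less than its bootstrap SD. With 1 library per group that SD holds no spread between libraries. These genes are short (median 1848 bases against 3698). For TGF-b1+DP against DMSO their median was -0.0792, although that culture also received TGF-b1. A TGF-b1 library that stands apart and an effect of TGF-b1 that is absent with DP would both give this. A property of 1 library that depends on length or abundance and an effect of TGF-b1 therefore cannot be told apart, and both may contribute.

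The opposite course of genes between the comparisons could reflect DP or a TGF-b1 library that stands apart. The correlation of -0.6827 lay below all 1000 shuffled values, which argues against 3 exchangeable libraries and not against 1 deviating library. After correction for length, GC content and abundance it was -0.544, between the bounds set beforehand and within the range of shuffled corrected values (-0.552 to -0.455), while with length and GC content alone it was -0.55, just below the lowest shuffled value of -0.546. With abundance included, the share of genes lower in TGF-b1 that were higher with DP was 46.4% (90 of 194), against 42.9% of 762 as deposited. The share of higher genes that were lower with DP was 36.6% (90 of 246), against 42.7% of 262. The sets of genes differ and no shuffled value is given for the corrected shares, so these shares do not decide between the explanations. With 1 library per group, a technical deviation of the TGF-b1 library and a reversal by DP cannot be told apart for these genes as a set.

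Shared reads are a candidate explanation for part of the largest TGF-b1 differences. Of the 20 named genes, 11 (55.0%) had an overlapping or near-identical measured gene, against 24.6% of genes of at least 5 FPKM. With EIF3C and EIF3CL, and NOMO2 and NOMO3, which are each other's partners, counted once per pair it was 9 of 18, and 3 of the 20 had no transcript that could be searched. EIF3C and EIF3CL summed to 103 FPKM in DMSO and 101 in TGF-b1 (log2 ratio -0.0233), so assignment of reads between the copies may have differed between libraries. The same reading fails for NOMO1 (chosen after its values were seen), NOMO2 and NOMO3, whose sum was 91.9 FPKM in DMSO, 24.4 in TGF-b1 and 93.0 with DP, and no biological explanation was tested.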
